A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

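The measurements were competitive hybridisations of cDNA from 2 immunoprecipitates of Saccharomyces cerevisiae on spotted arrays with 2 channels. In each, RNA that came down with zz-tagged Yra1 was set against RNA that came down with the zz tag alone, per the labels. The 5 arrays formed 1 group and are called arrays 1 to 5, after their replicate numbers. The zzYra1 immunoprecipitate was in channel 2 on arrays 1, 2 and 5 and in channel 1 on arrays 3 and 4, per the labels. Arrays 4 and 5 carry the same day in their labels and have opposite orientations. Whether they came from the same RNA is not given in the sources used here, and neither is whether any arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

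The deposited values were log10 ratios of the channels, with 1 column per array in 2 tables. The scale was not stated in the labels and was settled from the deposited values. Of 400 values drawn per array, between 22.5% and 94.25% became a ratio of whole numbers with a denominator of at most 3000 when taken as log10. For a base of 2 that share was between 0.25% and 1.25%, and for natural logarithms between 0% and 0.5%. The deposited columns were not centred: their medians were 0.800, -0.343, 0.0482, 0.478 and 0.478 log10 units on arrays 1 to 5. The scanner, the background correction, the dyes, the reason for missing values and which immunoprecipitate was the numerator are not given in the sources used here. No intensities were used here, so signal over background is unknown, and the number of arrays limits the precision.

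The table of arrays 1 to 3 held 7680 spots, of which 6695 had 1 gene symbol and 985 had none. The table of arrays 4 and 5 held 12800 spots, of which 11138 had 1 gene symbol and 1662 had none. No spot had several gene symbols. Symbols were updated through the gene identifiers to the R64 reference gene table, which matched 5578 of 5583 genes of the first table and 5534 of 5539 genes of the second. Because the files name no genome build, no coordinates are given. A few rows with a repeated spot number were averaged, and 1 row without a numeric spot number was left out. All columns of values were used.

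Deposited values were multiplied by 3.32 to give log2 ratios, averaged over the spots of a gene, and centred on the median gene of each array. No loess, quantile or scale normalisation was applied, because many RNAs may truly shift one way in an immunoprecipitation. The centring itself removes a shift shared by most genes, so centred values show only differences from the median gene of an array. Which way the ratios run was to be settled by a rule fixed before the data were examined: the median Pearson correlation over pairs of arrays with opposite orientation had to be under -0.1 or over 0.1. It was -0.000449 over 6 pairs, so the direction stayed unsettled. Results are therefore given for arrays of one orientation apart, and for all 5 arrays under both readings. In the channel reading the ratio has the same channel as numerator on every array, and the signs of arrays 3 and 4 were turned. In the other reading the authors had already turned the values. Signs are those of the fitted values and do not say which immunoprecipitate held more of an RNA.

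Genes with a value on at least 4 of the 5 arrays were fitted in limma 3.58.1 under R 4.3.3, with the orientation as an additive term, so that the 2 readings are the 2 coefficients of one model. Moderated p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Where an array was left out, the filter was at least 3 arrays. Each table was also fitted alone, on genes measured on all of its arrays. Of 34 gene lists fixed before the data were examined, 31 had members on the tables. The name patterns of the lists for the mitochondrial genome, Ty elements and non-coding RNA matched no gene, after the Ty pattern was corrected because it had taken in unrelated genes, so these lists gave no result. Ty open reading frames named only by their locus, such as YBL005W-B and YAR009C, were on the tables but in no list; these examples were named after their values were seen. The annotation used here holds no exons, so intron-containing genes came from a list written by hand. Lists with at least 3 members measured on every array were tested with camera at an inter-gene correlation of 0.01. Lists of at least 5 genes on a table were also compared with the other genes for the share measured on each array, with Fisher's exact test (two-sided) and Wilson 95% intervals, adjusted over 155 tests. The median of a list on an array was placed among 10000 random lists of the same size. These were not matched on expression, because no intensities were used. Both comparisons take genes as independent, although gene copies with near-identical sequences can share a value, so they may overstate the evidence.

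The genes named are YRA1 and MEX67, then genes past the threshold, then, because none passed, the next 6 on each side by moderated t for each reading, and up to 3 members with the smallest p for each list described. Genes named outside this rule are said to be so. The fit was tested on simulated data made by shuffling the values of each array over its measured genes and adding known changes to 200 of 725 genes, 20 times. It recovered 6.20% of genes changed 2-fold, 45.2% of those changed 4-fold, 84.4% of those changed 8-fold and 95.2% of those changed 16-fold, with 0.550 false calls on average. Each added change had the same size on every array. With 200 genes changed at once the Benjamini-Hochberg cut-off is easier to pass, so these shares overstate recovery where few genes change. The alternatives tried were the reading of the direction, no orientation term, no centring, equal scale, other filters, probe medians, the shared-day arrays averaged, array weights, robust and trended variance, ranks, leaving out each array, and, added after seeing the data, centring by position on the slide. That centring took from each spot the median of its neighbours of other genes in a window of 7 by 7 spots. Spots with fewer than 5 measured neighbours were dropped. The grid of 20 spots per printed row was inferred from the lag at which values correlated again, and served both tables. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.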

Results

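RNA bound to Yra1, an adaptor protein of nuclear mRNA export in yeast, was compared with RNA recovered by the zz affinity tag alone on 5 arrays. The question was which transcripts co-purify with tagged Yra1. On arrays 1, 2 and 5 the zzYra1 immunoprecipitate was in channel 2, and on arrays 3 and 4 it was in channel 1. A value was deposited for 3125, 3515 and 7429 of 7680 spots on arrays 1, 2 and 3, and for 2535 and 2098 of 12800 spots on arrays 4 and 5. These covered 44.3%, 51.1%, 97.6%, 23.9% and 19.8% of the genes on the respective table. Of 5583 genes, 725 were measured on at least 4 arrays and 146 on all 5. The standard deviation of the log2 ratios over spots was 1.13, 0.96, 0.99, 2.51 and 1.17 on arrays 1 to 5, so that array 4 was the most variable.

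Genes of 4 lists (ribosomal proteins, glycolysis, cell wall and amino acid biosynthesis) were measured more often than other genes on at least 1 array. Cytosolic ribosomal protein genes had a value in 109 of 135 cases on array 2 (80.7%, 95% Wilson interval 73.3% to 86.5%), against 50.3% of other genes. On array 4 the share was 89 of 132 (67.4%, interval 59.0% to 74.8%) against 22.9%, and on array 5 it was 91 of 132 (68.9%, interval 60.6% to 76.2%) against 18.6%. The adjusted p of Fisher's exact test was 3.4e-11 on array 2, 8.2e-25 on array 4 and 5.1e-33 on array 5. Array 1 did not show this: 54 of 135 ribosomal protein genes were measured (40.0%, interval 32.1% to 48.4%) against 44.5% of other genes, with an adjusted p of 0.780. On array 3 nearly every gene had a value, and 133 of 135 ribosomal protein genes did. The tests and intervals take genes as independent, while many ribosomal protein genes are A and B copies that can bind the same cDNA. They may therefore overstate the evidence.

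The genes of glycolysis and fermentation were measured in 15 of 21 cases on array 4 (71.4%, against 23.8% of other genes, adjusted p = 0.00017 by Fisher's exact test) and in 18 of 21 on array 5 (85.7%, against 19.6%, adjusted p = 5.7e-09). On array 2 they were measured in 17 of 21 cases (81.0%, against 51.0%), which did not pass (adjusted p = 0.0899). Cell wall genes were measured more often on array 1 (40 of 62 genes, 64.5% against 44.1%) and on array 2 (44 of 62, 71.0% against 50.9%), each with an adjusted p of 0.0334. They were also measured more often on array 5 (25 of 61, 41.0% against 19.6%, adjusted p = 0.0035), but not past the test on array 4 (22 of 61, 36.1% against 23.8%, adjusted p = 0.289). Genes of amino acid biosynthesis passed on array 5 alone, with 27 of 72 measured (37.5% against 19.6%, adjusted p = 0.0107). Translation factors (adjusted p of 0.735 or more) and histones (0.0855 or more) passed on no array. No list was measured less often past the threshold on any array. The mitochondrial ribosomal protein genes were measured at 43.2%, 50.0%, 98.6%, 22.2% and 6.94% on arrays 1 to 5.

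**Figure D1:**
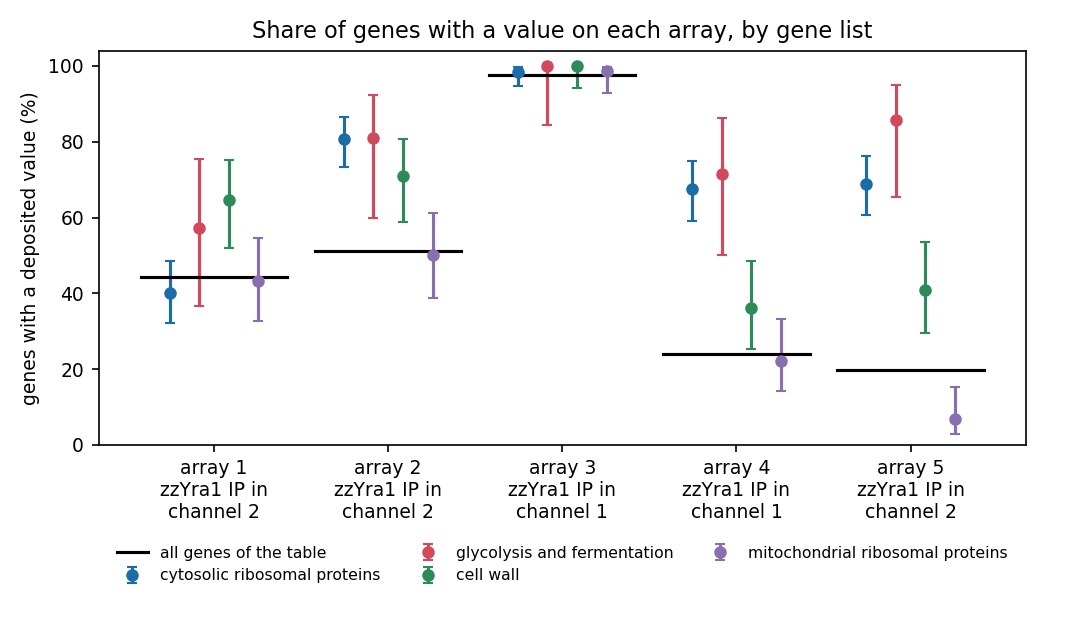
Percentage of genes with a deposited value on each of the 5 arrays (vertical axis) for 4 gene lists, with Wilson 95% intervals as bars, and for all genes of the table as black lines. Ribosomal protein genes lay at 80.7%, 67.4% and 68.9% on arrays 2, 4 and 5, above the lines, and at 40.0% on array 1, where the line was at 44.3%.

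Among the genes that were measured, the ratios of whole groups lay apart from the rest on single arrays. On array 2 the median ribosomal protein gene lay 0.56 log2 units below the array median (-0.56), with 79 of 109 members below it, and all 10000 random lists of the same size were higher. On array 4 the same list lay at 0.72, and 88 of 10000 random lists were higher. Over arrays 1 to 5 its medians were -0.03, -0.56, 0.05, 0.72 and 0.15, and those of the glycolysis genes were 0.42, -0.46, -0.03, 1.30 and 0.18. On array 4, 13 of 15 glycolysis genes were above the array median. Cell wall genes lay at 0.52 on array 2, with 30 of 44 members above the array median, and 2 of 10000 random lists were higher. On array 4 their median was 0.81, which 805 random lists exceeded. Genes of cytosolic chaperones and the heat shock response had a median of 0.52 on array 1 and -0.43 on array 2. With each spot set against its neighbours on the slide, a step added after seeing the data, the ribosomal protein medians were -0.01, -0.49, 0.07, 1.03 and -0.01 on arrays 1 to 5, those of glycolysis were 0.26, -0.59, -0.07, 1.67 and -0.27, the cell wall median on array 2 was 0.28, and the chaperone median on array 1 was -0.05. That step dropped spots with fewer than 5 measured neighbours, so its medians on arrays 4 and 5 rest on fewer genes. They came from 63 of 89 and 60 of 91 ribosomal protein genes, and from 8 of 15 and 12 of 18 glycolysis genes. Each of the medians given here comes from a single array and is a description of that array. Of 145 list medians, 12 fell outside the central 95% of random lists, where 7.25 would by chance.

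The arrays did not share a pattern across genes. Pearson's r across genes lay between -0.0816 and 0.0468 over the 10 pairs of arrays. The 4 pairs of the same orientation gave values between -0.0816 and -0.0181, and the 6 pairs of opposite orientation between -0.0422 and 0.0468. Genes are not independent replicates, and these values describe the arrays. The ratios of arrays 4 and 5, of the same day, correlated at 0.0468 over 546 genes. On arrays 4 and 5, which have adjacent duplicate spots of a gene, these correlated at 0.803 on array 4 (914 pairs) and at 0.863 on array 5 (737 pairs). The A and B copies of ribosomal protein genes, which have near-identical sequences and can bind the same cDNA, correlated at 0.83 on array 1 (10 pairs), 0.843 on array 2 (38 pairs), 0.527 on array 4 (26 pairs) and 0.536 on array 5 (33 pairs). On array 3 the same correlation was 0.0593 over 56 pairs. The adjusted p of the permutation test was 0.0216, 0.0005, 0.654, 0.00817 and 0.002 on arrays 1 to 5, and the unadjusted 0.0001 of array 2 is the smallest that 10000 permutations can give. Without the 2 most extreme pairs the correlations were 0.622, 0.638, -0.0761, 0.539 and 0.368, and by ranks over all pairs (Spearman) they were 0.273, 0.493, -0.0200, 0.599 and 0.568. On array 1 the value rests largely on RPL20A and RPL20B, at 6.23 and 5.96, which were named after their values were seen: without the 2 most extreme pairs its permutation p was 0.123, and by ranks 0.446, in tests added after seeing the data. Neighbouring spots of different genes also correlated, at 0.495, 0.268, 0.381, 0.564 and 0.377 on arrays 1 to 5.

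**Figure D2:**
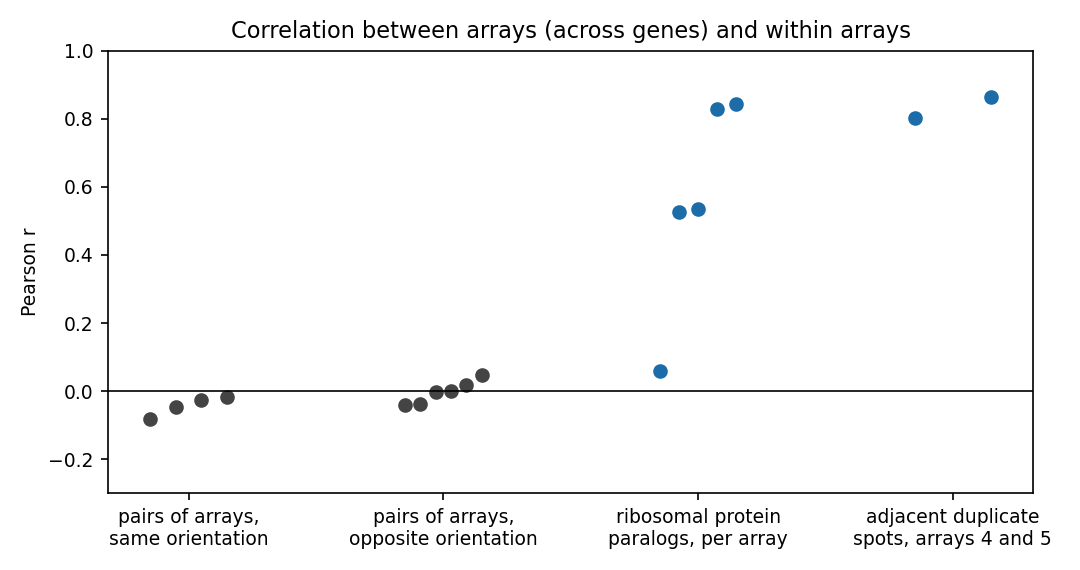
Pearson correlation (vertical axis) across genes for the 10 pairs of arrays, split by orientation, and within arrays for A and B copies of ribosomal protein genes (1 point per array) and for adjacent duplicate spots of a gene. The pairs of arrays lay between -0.0816 and 0.0468, and the duplicate spots at 0.803 and 0.863.

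No gene passed the threshold when all 5 arrays were fitted together, in either reading of the direction. YRA1 itself, the gene of the tagged protein, was measured on array 3 alone (0.63 log2 units from the array median). MEX67, the gene of the export receptor that binds Yra1, had values on array 1 (-1.07) and array 3 (0.16), so neither gene was tested. In the channel reading the cell wall glucanase gene BGL2 lay furthest from 0, at 3.00 ± 0.80 (log2, SE; limma adjusted p = 0.905), and its turned sign was the same on 5 of 5 arrays. Its values were 1.09, 5.32, -5.41, -0.72 and 2.38 on arrays 1 to 5 before turning. The polyamine oxidase gene FMS1 came next by moderated t, at 1.62 ± 0.55, the uncharacterised gene YLR046C at 1.60 ± 0.63, the ribosomal protein gene RPL16B at 1.67 ± 0.67, the proteasome gene RPN7 at 1.35 ± 0.54 and the ribosomal protein gene RPS14B at 1.25 ± 0.50. On the negative side were NPT1, of NAD salvage (-1.52 ± 0.48), SIS2, a regulator of the phosphatase Ppz1 (-1.92 ± 0.65), YCL068C (-1.71 ± 0.60), CIS3, a cell wall glycoprotein gene (-1.29 ± 0.47), EMC6, of the endoplasmic reticulum membrane complex (-1.38 ± 0.51), and RPS29B (-1.33 ± 0.50). All 12 had an adjusted p of 0.905.

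**Figure D3:**
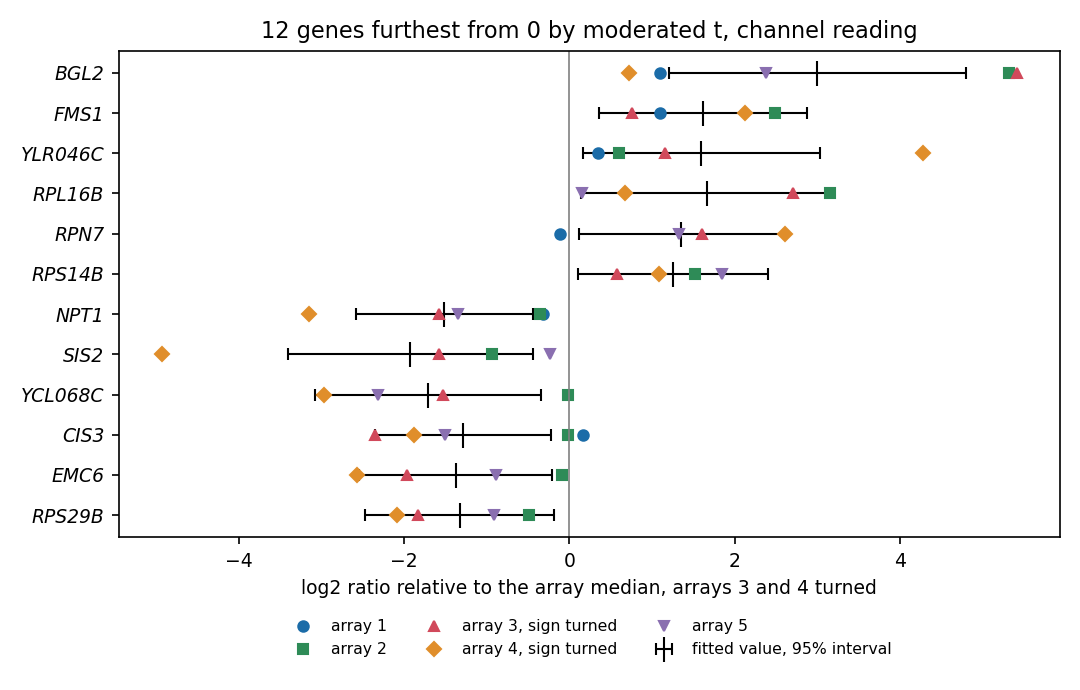
Log2 ratio relative to the array median (horizontal axis) of 12 genes in the channel reading, with the signs of arrays 3 and 4 turned. Symbols are single arrays, and vertical ticks with bars are the fitted values with 95% intervals, which for BGL2 ran from 1.20 to 4.79; none passed the adjusted threshold.

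In the other reading the 6 genes with the highest moderated t were RPP0, of the ribosomal stalk (1.58 ± 0.49), the nuclear transport factor gene NTF2 (2.03 ± 0.67), the tropomyosin gene TPM1 (1.62 ± 0.55), POP4, of ribonuclease P (1.54 ± 0.55), RPL5 (1.78 ± 0.63) and the chaperonin gene CCT5 (1.76 ± 0.64). The 6 with the lowest were VHS3, a relative of SIS2 (-1.42 ± 0.54), AIP5 (-1.43 ± 0.54), the Aurora kinase gene IPL1 (-1.76 ± 0.69), the Ras regulator gene IRA1 (-1.35 ± 0.54), SDS24 (-1.23 ± 0.51) and the mating pheromone gene MFA1 (-1.32 ± 0.54). Each had an adjusted p of 0.903. Of 725 genes tested in limma, 19 had an unadjusted p under 0.05 in the channel reading and 25 in the other, and shuffled values gave 22.95 on average, with a range of 14 to 31 over 20 runs. The median half-width of the 95% interval was 1.32 log2 units. Leaving out array 3 gave 68 calls in the channel reading and 80 in the other, but none when the arrays were first scaled to equal spread, a setting added after seeing the data. When an array was left out, genes with a value on at least 3 of the other 4 were tested, which also took in genes outside the fit of 5 arrays. In the channel reading this gave 2 calls of 1811 genes without array 4, BGL2 (4.17) and RPL16A (3.71), and 1 of 1098 without array 2, THI11 (4.28), while the other reading gave 0 in each case. RPL16A and THI11 were not among the 725 genes. On the genes of the fit of 5 arrays, a setting added after seeing the data, there were 3 calls without array 4 (BGL2, DOG2 and EDC2) and 0 without array 2. RPL16A, THI11, DOG2 and EDC2 were named after their values were seen. Where array 3 or array 4 is left out, the other is the only array of its orientation and adds nothing to the residual spread.

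Arrays of one orientation, taken apart, gave no call either. Over arrays 1, 2 and 5, 281 genes were tested in limma, 6 had an unadjusted p under 0.05, and the smallest adjusted p was 0.821. Over arrays 3 and 4, 1300 genes were tested, 65 had an unadjusted p under 0.05, and the smallest adjusted p was 0.807. BGL2 lay at 2.93 ± 0.86 over arrays 1, 2 and 5.

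Within each table alone no gene passed. The table of 3 arrays gave 55 of 1282 genes with an unadjusted limma p under 0.05 in the channel reading and 45 in the other. The table of 2 arrays gave 14 and 34 of 546 genes. Without array 1, 2795 genes had values on arrays 2 and 3, and there were 19 calls in the channel reading and none in the other; on the 1282 genes alone, a setting added after seeing the data, there were 2, BGL2 and EDC2. BGL2 (5.37), RPL16A (4.15), EDC2 (3.83), YER187W (3.59), RPL21B (2.99) and RPL16B (2.93) led these 19. RPL16A, EDC2, YER187W and RPL21B were named after their values were seen.

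The gene lists did not move past the test in either reading. Of 77 ribosomal protein genes tested, 36 had a positive value in the channel reading and 54 in the other, none passed, and none did when adjusted over the list alone. Their median was -0.05 and 0.24 in these readings. In the channel reading RPS29B, RPL16B and RPS14B had the smallest p among these genes. Of 16 glycolysis genes 5 were positive in the channel reading, with PFK2 (-1.24), HXK1 (-1.12) and CDC19 (-1.32) closest to the threshold. In the other reading 10 of 16 were positive, with a median of 0.40, and CDC19 lay at 2.18. Of 21 cell wall genes 12 were positive in the channel reading, led by BGL2 (3.00), CIS3 (-1.29) and GAS5 (-1.02), and 10 in the other, where these 3 lay at -0.07, 0.83 and 1.71. In the mRNA export list, which holds the partners of Yra1, 5 genes were tested and none passed, with HRP1 (-1.61), YRA2 (-0.87) and GBP2 (0.40) closest in the channel reading; these lay at 1.48, 0.55 and 0.47 in the other. Camera could test 7 lists on genes measured on every array, and 0 passed. The lowest adjusted p was 0.461 in the channel reading and 0.514 in the other. With an estimated correlation it was 0.748 and 0.662. Fry called 0 of the 7 lists, with 1 list, ergosterol synthesis, at an unadjusted p of 0.0333 in the channel reading.

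Intron-containing genes lay 0.27 log2 units above other genes on average in the channel reading, over 19 and 706 genes. The permutation p was 0.0923, two-sided, and camera gave p = 0.636 over the 5 members measured on every array. None of the 19 was a ribosomal protein gene, while the 706 held ribosomal protein genes, some of which have introns; without ribosomal protein genes the difference was 0.25, over 19 and 629 genes, with a permutation p of 0.112. In the other reading the difference was -0.09, with a permutation p of 0.573. MMS2 (1.25), HNT1 (0.97) and LSB3 (1.27) had the smallest p among them in the channel reading.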

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

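The tests of explanations in this part were chosen after the results were seen. Among 63 sets of values over 4 or 5 arrays, 6 had 1 array far from the others, where chance gives about 1 in 20, or 3.15.

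Array 4 had a standard deviation of 2.51 log2 units over spots, while the others lay between 0.96 and 1.17. Array 4 also stood apart in the medians of 4 gene lists, where its wider spread alone moves medians of few genes. Genes of cyclins and the G1/S transition lay at -1.57 there, against -0.21 to 0.18 on the others, with 903 of 10000 random lists of array 4 lower. Genes of mating and the pheromone response lay at -1.67, against 0.05 to 0.30 on 3 others, with 705 lower. Purine and pyrimidine synthesis genes lay at -2.10, against -0.42 to 0.10, with 201 lower. Genes of trehalose, glycogen and oxidative stress lay at 0.81, against -0.20 to 0.08, with 1455 higher. Array 5 stood apart in the splicing genes, with a median of -0.73 against -0.09 to 0.16 and 882 random lists lower. With each spot set against its neighbours these 5 medians were -1.56, -0.44, -2.29, 1.44 and -0.16. They then rested on 6, 4, 6, 10 and 4 genes, against 7, 6, 9, 13 and 5 before.

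The ratios of genes did not correlate between arrays. A trend over the slide surface, wider than adjacent spots, that hid a shared effect is argued against. After each spot was set against its neighbours, the largest absolute correlation over the 10 pairs was 0.0581. Adjacent spots of different genes still correlated at 0.120 to 0.200 after this step, so a position effect at that scale was not removed. Spot noise within arrays 4 and 5 is argued against as the whole cause, because adjacent duplicate spots still correlated at 0.619 or more after the same step. A mismatch of all rows and genes on array 3 is argued against by the extreme genes it shared with array 2. After slide-position centring these gave an exact p of 2.4e-04 at tails of 2%, Bonferroni-adjusted over 120 counts. A mismatch of some rows stays open, because the ribosomal protein copies on array 3 correlated at only 0.0593. Whether noise of dim spots would also give this value was not tested, because no intensities were used. With 1 group of arrays no biological explanation was tested, and differences between the immunoprecipitates hybridised stay open.

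Ribosomal protein genes were measured more often on arrays 2, 4 and 5. A brightness filter that left dim spots without a value on these arrays stays open, because no intensities were used. The lists with abundant transcripts did not all pass: glycolysis genes were measured more often past the test on 2 of the 3 arrays, translation factor and histone genes on none. The histone list is short, with 5 of 10 genes measured on array 2 (51.1% of other genes), 5 of 10 on array 4 (23.9%) and 6 of 10 on array 5 (19.8%). The same filter is argued against on array 1 if its rows name the right genes and the same RNAs were bright, because 40.0% of ribosomal protein genes were measured there. A mismatch of rows and genes on array 1 stays open, because the correlation of 0.83 between ribosomal protein copies rests on few pairs (0.622, permutation p = 0.123, without the 2 most extreme). With 1 group no biological explanation was tested, so more binding of these RNAs in either immunoprecipitate stays open.

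Arrays 2 and 3 shared extreme genes of opposite sign: BGL2, EDC2, RPL16A, RPL16B, RPL21B, SAS3, SWA2 and YER187W were among the 2% of genes at the ends of both, 8 genes where 2.24 would by chance. At tails of 2%, chance is argued against by an exact p of 2.4e-04, Bonferroni-adjusted over 120 counts (20 for each of 3 tail sizes, before and after slide-position centring). This lowest p came after that centring, where the exact p adjusted over 20 counts was 0.0458 at 1%, 4.0e-05 at 2% and 0.849 at 5%. Before the centring it was 0.0452 at 1%, 0.0342 at 2% and 0.780 at 5%. The argument thus depends on the size of the tail, and copies such as RPL16A and RPL16B were counted as separate genes. After each spot was set against its neighbours, r between adjacent spots of different genes was still 0.161 on array 2 and 0.180 on array 3. Between spots 2 places apart it was -0.006 and 0.055. A trend over the slide surface wider than adjacent spots is argued against, because 12 genes were shared after that step. An effect bound to the channel at these spots cannot be told apart from an effect of the immunoprecipitate, because the numerator of the ratios is not stated; on arrays 1, 4 and 5, 9 of 14 measurements of these genes followed the channel (exact binomial p = 0.424). BGL2 followed it on 3 of 3. SAS3 and SWA2 were named after their values were seen.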

How the results depend on the processing

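Each log ratio already pairs both immunoprecipitates of its array, and the arrays form 1 group, so no further pairing was made. The shared day as a random block was not run, because the single pair of arrays gave an estimated correlation for 0 genes. Of 112 alternatives of the comparisons 100 kept the result. Leaving out each array, with a filter of at least 3 arrays, gave 0 to 68 calls in the fit of 5 arrays in the channel reading, and 0 to 80 in the other. Without array 4, array 3 is the only array of its orientation and so adds nothing to the residual spread. The highest counts came without array 3, where the same holds for array 4, the most variable. With arrays scaled to equal spread, the same fit gave 0 calls in both readings. In the channel reading there were 2 calls without array 4 and 1 without array 2, against 0 and 0 in the other. On the genes of the fit of 5 arrays, added after seeing the data, there were 3 and 0, and 68 without array 3 (80 in the other reading). In the table of 3 arrays leaving out each array gave 0 to 19 calls, the 19 coming without array 1, where 2795 genes were tested; on the 1282 genes of all 3 arrays there were 2. With the values of array 3 shuffled over the 2795 genes, 0 of 100 draws gave as many as 19 calls. The shuffled draws gave 3.35 calls on average and 15 at most, so this fit makes calls without a shared effect. In the table of 2 arrays, no centring in the other reading gave 35 calls, because both columns have a median of 0.478 log10 units. Centring by slide position, added after seeing the data, gave 1 call there in the channel reading (ERD1), and equal scale gave 1 in the other (TAF2). The cause was not tested, and both genes were named after their values were seen. Gene lists gave 0 calls under every alternative run. In the channel reading the intron difference lay between 0.18 and 0.30 when each array was left out; the other reading was not run. Of 168 alternatives of named genes 155 kept the direction and stayed past no threshold, and the rest kept the direction and passed it without array 3 or array 4. Of 25 list medians on single arrays 20 moved by less than their sampling error under centring by slide position, and 15 of 15 measured shares stayed within their intervals when spots were counted. The genes shared at the ends of arrays 2 and 3 numbered 4 at 1% (0.561 by chance, unadjusted exact p = 0.00226, 0.0452 over 20 counts) and 21 at 5% (14.03 by chance, 0.0403 and 0.780), so the call depends on the size of the tail. With no intensities, what signal over background limits is unknown.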

Other observations

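The tests in this part were chosen after the data were seen. On array 3, where nearly every gene had a value, the histone genes had a median of 0.67 log2 units, with 8 of 10 members above the array median, and 196 of 10000 random lists were higher. Genes of protein folding and translocation in the endoplasmic reticulum lay at -0.39 on the same array, with 142 random lists lower. On array 2, genes of transcription factors with few transcripts per cell had a median of 0.41. Intron-containing genes, from a list that leaves out almost all ribosomal protein genes, had one of 0.29. Both lay on the side opposite to the ribosomal protein genes. Some of the ribosomal protein genes have introns too, so this is no contrast by introns. With each spot set against its neighbours these medians were 0.78, -0.21, 0.40 and 0.14. These arrays were picked for their values. Before that step the histone medians were -0.67, 0.67, 0.91 and 0.07 on arrays 2 to 5, and on arrays 1 to 5 those of endoplasmic reticulum folding were -0.01, -0.18, -0.39, 0.06 and 0.04, those of the transcription factors -0.21, 0.41, -0.25, 0.57 and -0.28, and those of intron-containing genes 0.05, 0.29, -0.20, -0.13 and 0.33.

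The copies RPL16A and RPL16B, which encode the same ribosomal protein, lay at 3.81 and 3.15 on array 2 and at -4.48 and -2.70 on array 3. RPL16A was at 2.06 on array 5, and RPL16B at 0.15 there and -0.67 on array 4. RPL21A and RPL21B also lay together on array 2, at 3.86 and 3.67, but apart on array 3, at 1.78 and -2.32. Both pairs were picked for these values.

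Which genes were measured went together most on arrays 4 and 5, which share both the day and the table, so these cannot be separated. The phi coefficient between measured genes of this pair was 0.30, and that of the other pairs lay between -0.0220 and 0.0763, the highest for arrays 2 and 5.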
